A study of Mus musculus with 12 samples.

How the data were processed

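Tumours grown in Balb/c mice from 4T1 cells, a mouse mammary carcinoma line that metastasises spontaneously, were compared between mice restrained for 2 hours a day on 28 days in a row and mice left untreated. All tumours were taken 35 days after inoculation and frozen on dry ice. RNA was extracted with Trizol and sequenced on an Illumina HiSeq 2500, per the labels' protocols. Each group had 3 mRNA libraries and 3 miRNA libraries, 12 in all, and the group and the replicate number of each library came from its title. The labels do not say that each tumour came from a separate mouse, nor that the mRNA and the miRNA library of one number came from the same tumour. The p-values therefore measure the spread between these libraries.

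The deposited mRNA table is named as raw counts, but its values are log2 values that the authors had already normalized. They were fractional, ran from -1.97 to 17.85, and were exactly 0 either in all 6 libraries or in none. The spread between libraries shrank towards 0 at low expression: the median range over the 6 libraries was 0.262 for genes with a mean log2 value of 9 to 10 and 0.0775 for those with a mean of 2 to 3. A regularized log transform gives such shrinkage, though the transform used is not stated. The base of the logarithm is not stated and was taken to be 2, the base of that transform. The values as powers of 2 summed to between 1.69e+07 and 1.77e+07 per library, in the range of read numbers, as powers of e to at least 7.98e+08 and as powers of 10 to at least 1.04e+18. The submitters' processing notes name bcl2fastq, kallisto 0.46.1 and the mouse build mm10; the step from kallisto's estimates to these values is not given in the sources used here. Because of the shrinkage, fold changes from this table are likely to understate the change of weakly expressed genes, and the sequencing depth behind the values is unknown.

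The deposited miRNA table holds whole read counts per mature miRNA and precursor. The tool that counted miRNAs is not given in the sources used here. The table had 2128 rows for 1978 mature miRNAs, and 85 of these stood on more than 1 precursor row with nearly the same reads, so the precursor row with the highest total was kept for each. The totals were then 2090783, 2772685 and 3202224 counts in control replicates 1 to 3, and 2674483, 2010794 and 1738056 in stress replicates 1 to 3. A single miRNA, miR-21a-5p, took between 41.7% and 45.2% of them. Intervals on single counts are exact Clopper-Pearson intervals at 95%. The reads carry no molecular identifiers, so these intervals cover counting error only. Among the miRNAs, 10 sets of names with at least 60 reads had identical counts in every library and cannot be told apart; none of them is named here.

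The mRNA table had 35453 rows, of which 12658 were listed at 0 in all libraries and 26 bore a calendar date in place of a gene symbol. Both kinds were left out, which left 22769 genes, 22169 of them with a symbol in GENCODE M21. The test planned for this table was edgeR on counts. As the values are log2 values, limma 3.58.1 was used in its place (lmFit and eBayes with a variance trend and robust estimation) on 14098 genes with a mean log2 value of at least 4, a filter set after the unit was known. All tests ran in R 4.3.3, with DESeq2 1.42.0 for the alternatives. The miRNA counts were tested as planned, with edgeR 4.0.16 (TMM normalization, filterByExpr, robust quasi-likelihood fit) on 462 miRNAs. Every test was two-sided and compared stress with control without covariates. P-values were adjusted by Benjamini and Hochberg's method over all features of a table, with 0.05 as the threshold. With 3 libraries against 3, an exact permutation test of a single value cannot go below p = 0.1.

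Before the data were examined, 24 gene lists and 8 miRNA lists were fixed, and each list with at least 3 tested members was compared with all other features by camera, with a preset correlation of 0.01 and, as an alternative, with a correlation estimated per list. A rule fixed at the same time chose the named genes. It took a set of EMT, STAT3 and stress-hormone genes in every case, and up to 8 called genes per direction whose groups did not overlap. Where fewer were called, it went on to the smallest p up to 5 per direction. It also took up to 4 called members of each list, or else the 2 with the smallest p. Genes named outside that rule were chosen after their values were seen and are marked so. Coordinates and 3' UTRs came from GENCODE M21 on GRCm38, the same assembly as mm10.

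Both fits were tested on simulated data. For stress against control in the mRNA table (14098 genes), 68% of 200 genes changed by 0.5 on the log2 scale were recovered, 87.5% of those changed by 1 and 93.5% of those changed by 2. For the miRNA table (462 miRNAs), 32% of 50 miRNAs changed by 1 were recovered, 96% of those changed by 2 and 94% of those changed by 3. False calls numbered 4, 8 and 13 genes and 0, 4 and 3 miRNAs. The simulation drew genes independently of each other, and miRNA counts with a dispersion smoothed over expression. The real libraries need not follow these settings, so the shares may overstate the recovery there. The alternatives covered the normalization, the filter on low values, the test, the threshold, the replicate number as a term, leaving out each library, and the genes of other cell types. Median centring, quantile normalization, a stricter filter and a fit without a variance trend for the mRNA table, sums over precursor rows for the miRNA table, and a muscle covariate for both were added after the data were seen. The list members Areg and Ahsp were not analysed here.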

Results

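The series measured mRNA and miRNA in 4T1 mammary tumours from mice under chronic restraint stress and from untreated mice, with 3 libraries of each kind per group. Its title names STAT3, miR-337-3p, the epithelial to mesenchymal transition (EMT) and metastasis. The comparisons therefore ask which mRNAs and miRNAs differed between stressed and control tumours, and where these genes and gene groups stood. The miRNA libraries held 1738056 to 3202224 counts. The mRNA values were deposited as normalized log2 values of unknown depth.

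In the stressed tumours 3 genes rose and 2 fell past the threshold. Hspa1b, a heat-inducible HSP70 chaperone, rose from a log2 value of 11.41 ± 0.20 (SD, n = 3) to 12.58 ± 0.12, a difference of 1.18 ± 0.11 (SE; 2.26-fold, limma adjusted p = 0.0399). Pnrc1, a nuclear receptor coactivator, rose by 0.82 ± 0.06 (1.76-fold, adjusted p = 0.0176), and Klhl24, a substrate adaptor of a ubiquitin ligase, by 0.49 ± 0.05 (1.40-fold, adjusted p = 0.0497). Heyl, a transcriptional target of Notch signalling, fell by 1.08 (SE 0.077; 2.12-fold lower, adjusted p = 0.0176). Olfml3, a secreted matrix protein, fell by 0.74 (SE 0.07; 1.67-fold lower, adjusted p = 0.0399). For each of the 5 genes all 3 stress libraries lay on one side of all 3 control libraries. Hspa1b on chromosome 17 (34956436 to 34959238) has a near-identical neighbour, Hspa1a (34969190 to 34972156), and reads of the pair cannot be divided with certainty. Hspa1a, named after its values were seen, stood 1.15 higher, with an adjusted p of 0.0619.

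**Figure D1:**
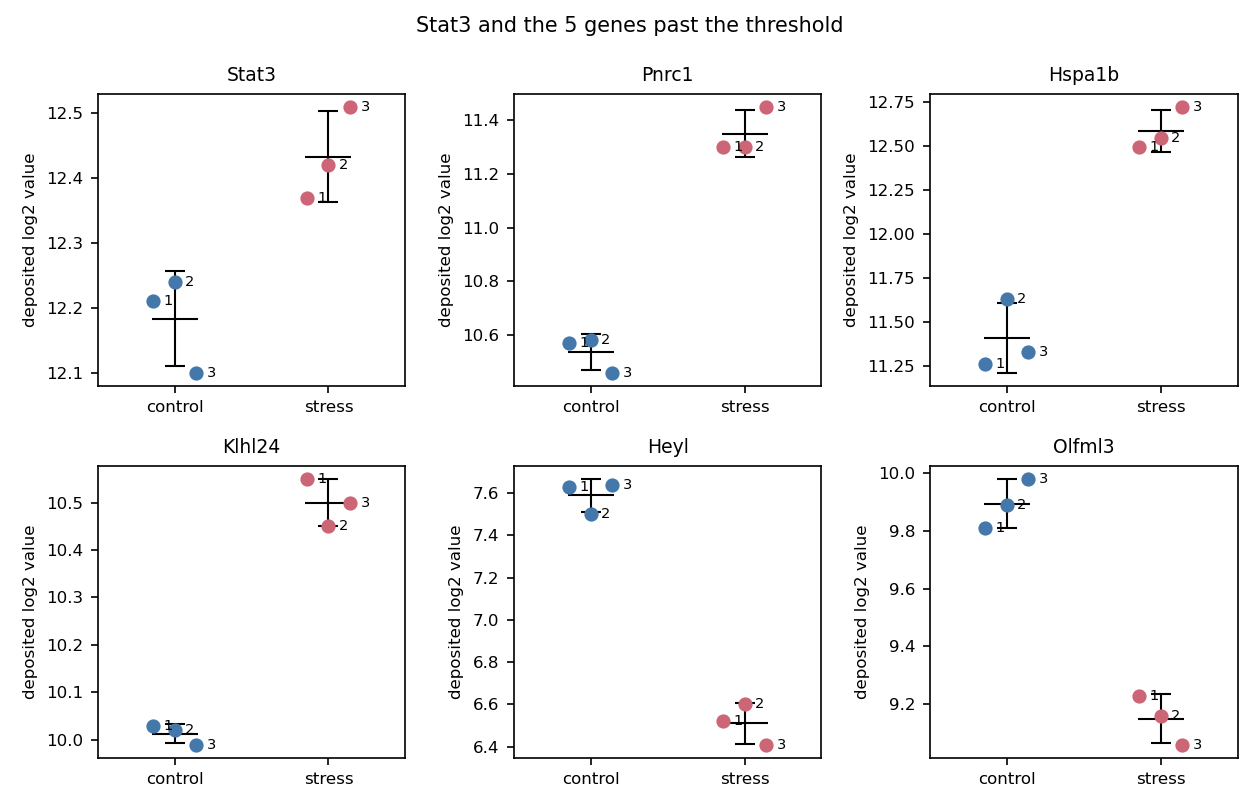
Deposited log2 values of Stat3 and of the 5 genes past the threshold in each control and stress library (points, numbered by replicate), with the mean (bar) and SD (whiskers) of 3 libraries per group. In each panel the 3 stress values lie on one side of the 3 control values; Stat3 itself, with an adjusted p of 0.138, did not pass the threshold.

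The next genes by p, none past the threshold, were Arid5b (0.42 higher, adjusted p = 0.0618), a regulator of adipogenesis, and the splicing factor Rbm39 (0.40 higher, adjusted p = 0.0618). On the lower side they were Cdh11, a cadherin of mesenchymal cells (-0.97, adjusted p = 0.0607), Cdr2 (-0.51, adjusted p = 0.0618) and mt-Nd3, a mitochondrially encoded subunit of complex I (-0.57, adjusted p = 0.0618). At an adjusted p of 0.1 the counts were 47 higher and 48 lower. The groups did not overlap in 24.3% of the 14098 genes, against 10% on average by chance. Genes vary together, so a single split can lie far from that average, and the share alone does not show an excess. After quantile normalization 3 genes were higher and 5 lower, and after median centring 2 and 2. No gene was called without control replicate 1 (adjusted p = 0.0669 for each of the 5 genes), control replicate 3 (0.148 to 0.308), stress replicate 1 (0.0961 to 0.162) or stress replicate 3 (0.0515 to 0.135), nor with a muscle covariate (0.289 to 0.501). With that covariate the differences stayed near their size and their errors grew: Hspa1b 1.14 ± 0.15 (SE), Pnrc1 0.72 ± 0.07, Klhl24 0.47 ± 0.07, Heyl -1.03 ± 0.10 and Olfml3 -0.63 ± 0.07. The Klhl24 and Olfml3 calls also ended without control replicate 2 (both 0.115), and those of Hspa1b, Klhl24 (both 0.0683) and Olfml3 (0.0754) without stress replicate 2. The Klhl24 call ended as well without the filter on low values (0.0626), without a variance trend (0.0712) and after median centring (0.0540).

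Stat3, on the minus strand of chromosome 11 (100885098 to 100939540), had a log2 value of 12.18 ± 0.073 (SD, n = 3) in control and 12.43 ± 0.071 in stressed tumours. The difference of 0.25 ± 0.06 (SE; 1.19-fold) had an adjusted p of 0.138 and did not pass the threshold, although all 3 stress libraries were above all 3 control libraries. The 28 fixed STAT3 target genes were called higher as a list: 19 of 27 tested members were higher and 8 lower, with a mean difference of 0.18 (camera adjusted p = 0.0167, adjusted p = 0.482 with an estimated correlation). None of them passed over all genes, while 5 higher and 1 lower passed adjusted over the list alone. Among these, Bcl2l1, an inhibitor of apoptosis, was 0.35 higher (adjusted p = 0.0976 over all genes), and Birc5, an inhibitor of apoptosis that peaks in mitosis and also stands in the proliferation list, was 0.34 lower (-0.34, adjusted p = 0.0947). The list shares 3 genes with the neutrophil list, S100a8, S100a9 and Lcn2. Without them the mean difference of the remaining 24 was 0.08 (camera adjusted p = 0.0929). The call of the full list also ended without control replicate 1 (mean 0.16, adjusted p = 0.104) and without stress replicate 3 (mean 0.11, adjusted p = 0.0791). It ended with a muscle covariate too (mean 0.10, adjusted p = 0.163). The IL-6 family and JAK-STAT components were not called (13 of 21 higher, adjusted p = 0.125, adjusted p = 0.464 with an estimated correlation); 3 higher and 1 lower passed adjusted over the list alone and none over all genes. The list was called without control replicate 3 (adjusted p = 0.0410) and with a muscle covariate (adjusted p = 0.0449). Their smallest p-values belonged to Osmr, a receptor of oncostatin M (0.49 higher, adjusted p = 0.104), and the kinase Jak2 (0.33 higher, adjusted p = 0.120).

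The mesenchymal EMT markers were called lower in stress: 16 of 22 were lower, with a mean difference of -0.17 (adjusted p = 0.0376, adjusted p = 0.593 with an estimated correlation). None passed over all genes, and 2 lower members passed adjusted over the list alone. These were Zeb1, a repressor of E-cadherin (-0.67 ± 0.15, adjusted p = 0.120), and Tnc, the matrix protein tenascin C (-0.64, adjusted p = 0.116). The call ended without control replicate 2 (mean -0.08, adjusted p = 0.186) and without stress replicate 2 (mean -0.09, adjusted p = 0.360). Without control replicate 1 the mean was -0.24, still called. The list holds genes that stromal cells also express, such as Tnc, and the fibroblast and collagen list was lower in the same libraries, by a mean of -0.47. Of the other EMT genes fixed in advance, Vim was 0.27 ± 0.17 higher (adjusted p = 0.433), Fn1 0.20 ± 0.10 higher (adjusted p = 0.349), Zeb2 0.08 higher (adjusted p = 0.530) and Twist1 0.07 higher (adjusted p = 0.827). Snai1 (-0.15, adjusted p = 0.484), Snai2 (-0.11, adjusted p = 0.481), Cdh2 (-0.09, adjusted p = 0.744) and Mmp9 (-0.54 ± 0.45, adjusted p = 0.562) were lower. E-cadherin, Cdh1, was at 11.78 ± 0.17 in control and 11.85 ± 0.13 in stressed tumours (adjusted p = 0.727). The epithelial markers were not called (14 of 25 higher, mean 0.03, adjusted p = 0.209), and no member passed either adjustment. The epithelial mean ran from -0.0226 without stress replicate 1 to 0.0837 without stress replicate 2, where the list was called (adjusted p = 0.0193). The tight-junction protein Ocln (0.31 higher, adjusted p = 0.135) and the keratin Krt7 (-0.36, adjusted p = 0.221) had the smallest p-values.

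The glucocorticoid list holds genes induced by these adrenal hormones, which are released under stress, and their receptor gene. Ddit4 stands both in it and in the hypoxia and glycolysis list. The glucocorticoid list was called higher: 17 of 20 tested members were higher, with a mean difference of 0.27 (adjusted p = 6.61e-06, adjusted p = 0.464 with an estimated correlation). None passed over all genes and 7 passed adjusted over the list alone. Examples are the repressor Bcl6 (0.52 higher, adjusted p = 0.0769) and the transcription factor Klf9 (0.75 higher, adjusted p = 0.120). Fkbp5, a co-chaperone of the glucocorticoid receptor, was 0.23 ± 0.06 higher (adjusted p = 0.147), Tsc22d3 0.27 higher (adjusted p = 0.255) and the receptor gene Nr3c1 0.15 higher (adjusted p = 0.234). Adrenergic receptors and cAMP-responsive genes were not called (7 of 15 higher, adjusted p = 0.900), and no member passed either adjustment. Their median was -0.05 and their mean 0.01. The members with the smallest p, Per1 (0.66 higher, adjusted p = 0.165) and Dusp1 (0.41 higher, adjusted p = 0.260), belong to the glucocorticoid list too.

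Proliferation genes were called lower: all 25 members were lower, with a mean difference of -0.27 (adjusted p = 5.96e-17, adjusted p = 0.464 with an estimated correlation). None passed over all genes and 22 passed adjusted over the list alone, among them the ribonucleotide reductase subunit Rrm2 (-0.45, adjusted p = 0.0647) and the mitotic kinase Plk1 (-0.45, adjusted p = 0.0769). Hypoxia and glycolysis genes were called higher: all 20 were higher, with a mean of 0.50 (adjusted p = 1.54e-12, adjusted p = 0.464 with an estimated correlation), and 15 passed adjusted over the list alone but none over all genes. Pfkfb3, which drives glycolytic flux, was 0.59 higher (adjusted p = 0.0647), and Pdk1, an inhibitor of pyruvate dehydrogenase, 0.43 higher (adjusted p = 0.104). The unfolded protein and heat shock genes were called higher (13 of 16, mean 0.25, median 0.14, adjusted p = 7.37e-05, adjusted p = 0.464 with an estimated correlation). Among these Hspa1b passed over all genes, and 5 passed adjusted over the list alone. Hspa1b and Hspa1a, whose reads may be shared, had the largest differences (1.18 and 1.15).

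Smaller shifts were called for 3 further lists. Type I interferon genes were higher (17 of 20, mean 0.13, adjusted p = 0.00892), with Rsad2 0.57 higher (adjusted p = 0.200) and Usp18 0.26 higher (adjusted p = 0.255). Cytosolic ribosomal protein genes were higher (24 of 26, mean 0.08, adjusted p = 0.00956), and Rps18, the member with the smallest p, was lower (-0.25, adjusted p = 0.131). Mitochondrially encoded genes were lower (10 of 13, mean -0.10, adjusted p = 0.0371), and mt-Nd3 and mt-Nd5 (-0.28, adjusted p = 0.159) were among 3 members that passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.661, 0.676 and 0.593 for these 3 lists. Each call ended when single libraries were left out: the interferon call without control replicate 1 (adjusted p = 0.0775), control replicate 2 (0.123) or stress replicate 2 (0.146), the ribosomal call without control replicate 2 (0.0707) or stress replicate 3 (0.494), and the mitochondrial call without control replicate 1 (0.255), stress replicate 1 (0.0697) or stress replicate 3 (0.0955). The ribosomal mean was 0.12 without stress replicate 2 and 0.0152 without stress replicate 3. The interferon mean was 0.22 without control replicate 3 and 0.21 without stress replicate 1. It was 0.07 without control replicate 2 and 0.08 without stress replicate 2. Without single libraries the mitochondrial mean ran from -0.135 to -0.0630. The ribosomal call also ended after quantile normalization (adjusted p = 0.135), and with a muscle covariate the list mean turned to -0.03 (adjusted p = 0.284). Antigen presentation genes were not called (9 of 14 higher, adjusted p = 0.355), with B2m 0.25 higher (adjusted p = 0.349) and H2-D1 0.21 higher (adjusted p = 0.354). They were called higher without control replicate 3 (0.12, adjusted p = 0.0322) and without stress replicate 1 (0.14, adjusted p = 0.00759). Their mean was below 0, and not called, without control replicate 2 (-0.05) and without stress replicate 2 (-0.04).

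**Figure D2:**
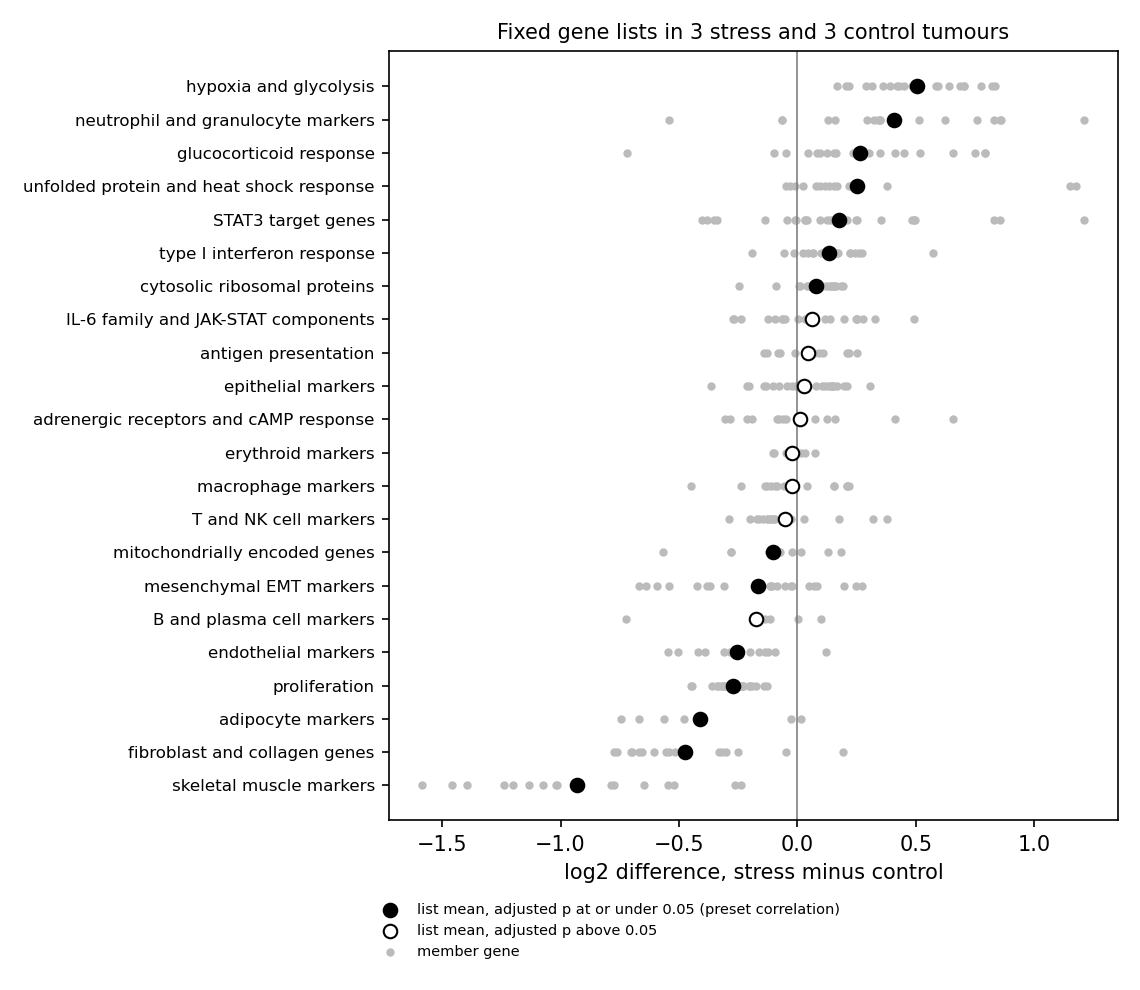
Log2 difference between 3 stress and 3 control tumours for the members (small grey points) and the mean (large points) of 22 fixed gene lists; filled points mark lists with a camera adjusted p at or under 0.05 with the preset correlation. Hypoxia and glycolysis genes (mean 0.50) stand at the upper end and skeletal muscle markers (mean -0.93) at the lower end; no list passed with an estimated correlation.

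Markers of stromal cells and surrounding tissue had lower group means in the stressed tumours. In the fibroblast, adipocyte and muscle lists, however, control replicate 1 lay among the stress libraries. Its fibroblast mean was 11.21, against 11.07 to 11.22 in stress, and its adipocyte mean 6.50, against 6.25 to 6.58. In the endothelial list all controls lay above all stress libraries. Fibroblast and collagen genes were called lower (17 of 18, mean -0.47, adjusted p = 1.96e-06, adjusted p = 0.464 with an estimated correlation), and 3 passed adjusted over the list alone, such as Thy1 (-0.49, adjusted p = 0.0769) and the smooth muscle actin Acta2 (-0.77, adjusted p = 0.111). The list mean was -0.30 without control replicate 2 and -0.21 with a muscle covariate, and the list stayed called in both. Endothelial markers were called lower (12 of 13, mean -0.26, adjusted p = 7.91e-05, adjusted p = 0.464 with an estimated correlation), and 3 passed adjusted over the list alone, including the VEGF receptor Kdr (-0.55, adjusted p = 0.106) and the angiopoietin receptor Tek (-0.39, adjusted p = 0.136). Adipocyte markers were called lower (5 of 6, mean -0.41, adjusted p = 0.0371, adjusted p = 0.593 with an estimated correlation), with Fabp4 at -0.67 (adjusted p = 0.146) and Lpl at -0.75 (adjusted p = 0.209). Of these, Fabp4 alone passed adjusted over the list alone. The list call ended without control replicate 2 (mean -0.23, adjusted p = 0.166) and without stress replicate 3 (mean -0.31, adjusted p = 0.208). With a muscle covariate the list was not called either (mean -0.11, adjusted p = 0.916). Without the filter on low values its mean was -0.22, still called. Skeletal muscle markers were called lower (all 16, mean -0.93, adjusted p = 2.81e-06, adjusted p = 0.482 with an estimated correlation), with no member past either adjustment. Their smallest p-values belonged to myoglobin, Mb (-0.55, adjusted p = 0.175), and the troponin Tnni2 (-0.27, adjusted p = 0.197). The muscle list mean was 8.43, 9.32 and 9.58 in control replicates 1 to 3 and 8.53, 8.66 and 7.35 in stress replicates 1 to 3. Without stress replicate 3 the mean difference was -0.52, still called. No member of the fibroblast, endothelial, adipocyte or muscle lists passed over all genes.

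Among immune cells, neutrophil and granulocyte markers were called higher (14 of 17, mean 0.41, adjusted p = 1.51e-05, adjusted p = 0.464 with an estimated correlation). Of these, 3 passed adjusted over the list alone and none over all genes: the G-CSF receptor Csf3r (0.62 higher, adjusted p = 0.0881), Clec4e (0.51 higher, adjusted p = 0.105) and S100a9 (1.21 higher, adjusted p = 0.159), the last outside the naming rule. The list mean was 0.25 without stress replicate 3 and 0.19 with a muscle covariate, and the list stayed called in both. T and NK cell markers (4 of 19 higher, adjusted p = 0.209), B and plasma cell markers (2 of 5, adjusted p = 0.615), macrophage markers (6 of 16, adjusted p = 0.796) and erythroid markers (3 of 6, adjusted p = 0.805) were not called, and no member passed. T and NK cell markers were called lower without control replicate 2 (-0.16, adjusted p = 0.00731) and without stress replicate 1 (-0.13, adjusted p = 0.0236). Their mean was above 0, and not called, without control replicate 3 (0.05), without stress replicate 3 (0.01) and with a muscle covariate (0.04). For macrophages the median (-0.05) and the mean (-0.02) were below 0, while the test pointed upwards. Their leading members were Cd5 (-0.12, adjusted p = 0.420) and Foxp3 (-0.20, adjusted p = 0.437), Ighm (-0.72, adjusted p = 0.333) and Cd22 (0.10 higher, adjusted p = 0.829), Cd68 (0.22 higher, adjusted p = 0.131) and Itgam (0.21 higher, adjusted p = 0.336), and Alas2 (-0.10, adjusted p = 0.607) and Hbb-bt (-0.10, adjusted p = 0.703). Skin keratinocyte markers and normal mammary gland markers had 2 and 1 tested members, too few for a list test: Krt10 (0.02 higher, adjusted p = 0.910), Sbsn (0.03 higher, adjusted p = 0.938) and Csn3 (-0.01, adjusted p = 0.957).

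Mature miR-337-3p was counted 11, 48 and 22 times in control replicates 1 to 3, and 3, 5 and 2 times in stress replicates 1 to 3. It comes from a 97-base precursor on the plus strand of chromosome 12 (109585789 to 109585885), between Meg3 (109541001 to 109571726) and Rian (109603940 to 109661716) in the imprinted Dlk1-Dio3 region. Mir3544 (109585813 to 109585873) is annotated on the opposite strand within it. The level was 9.91 ± 6.67 CPM (SD, n = 3) in control and 1.54 ± 0.595 CPM in stressed tumours. The edgeR log2 difference of -2.65 ± 0.63 (SE, 6.29-fold lower) had an adjusted p of 0.138 and did not pass the threshold, although the groups did not overlap. Nor did they overlap in 26.4% of the 462 miRNAs, against 10% on average by chance. A single split can lie far from that average, as miRNAs vary together. With edgeR, miR-337-3p passed without the filter on low counts (adjusted p = 3.90e-05) and without control replicate 1 (adjusted p = 0.0105). The unfiltered fit gave a like difference (-2.62 ± 0.52, SE) but an edgeR p of 5.21e-07, against 0.00349 with the filter. That p rested almost wholly on a spread pooled over miRNAs and hardly on that between the 3 libraries per group. With DESeq2, which applied its own filter on low counts, miR-337-3p also passed (-2.70, adjusted p = 0.0184). Over the alternatives the adjusted p ran from 3.90e-05 to 0.790, the highest with a muscle covariate. The counts are few: the exact 95% interval was 2.63 to 9.41 CPM of the total in control replicate 1 and 0.807 to 5.80 CPM in stress replicate 2, so these libraries overlap within counting error. The other arm, miR-337-5p, was at 92.1 ± 49.9 CPM in control and 37.5 ± 16.2 CPM in stressed tumours (-1.28 ± 0.47, adjusted p = 0.178).

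The other miRNAs of the Dlk1-Dio3 region stood lower with it. All 34 tested members were lower in stress, with a mean log2 difference of -1.46 (camera adjusted p = 3.59e-19, adjusted p = 0.374 with an estimated correlation). None passed over all miRNAs and 25 passed adjusted over the list alone, among them miR-540-3p (-2.23, adjusted p = 0.138) and miR-381-3p (-1.46, adjusted p = 0.138). With a muscle covariate the list mean was -0.54 and the list stayed called with the preset correlation. A linear fit of the list mean with that covariate gave -0.527, with a 95% interval of -2.34 to 1.28 that covers 0. The list mean was 4.91, 6.52 and 5.86 log2 CPM in control replicates 1 to 3 and 4.87, 4.71 and 3.67 in stress replicates 1 to 3, so that control replicate 1 lay beside the stress libraries. The same held for fibroblast and endothelial miRNAs, which were called lower (all 10, mean -0.96, adjusted p = 1.37e-05, adjusted p = 0.374 with an estimated correlation): control replicate 1 was at 10.16 log2 CPM, the other controls at 11.12 and 11.09, and the stress libraries between 9.74 and 9.99. In this list 7 miRNAs passed adjusted over the list alone and none over all miRNAs, including miR-143-3p (-1.24; 20651 ± 6987 against 8775 ± 514 CPM) and miR-145a-5p (-1.43), both abundant in smooth muscle and fibroblasts. Muscle miRNAs were called lower as well (all 5, mean -2.11, adjusted p = 0.00248, adjusted p = 0.374 with an estimated correlation), with no member past either adjustment. Values of the muscle-specific miR-499-5p (-1.61, adjusted p = 0.203) and miR-206-3p (-2.01, adjusted p = 0.212) had the smallest p. With limma-voom the list mean was -3.23, still called.

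**Figure D3:**
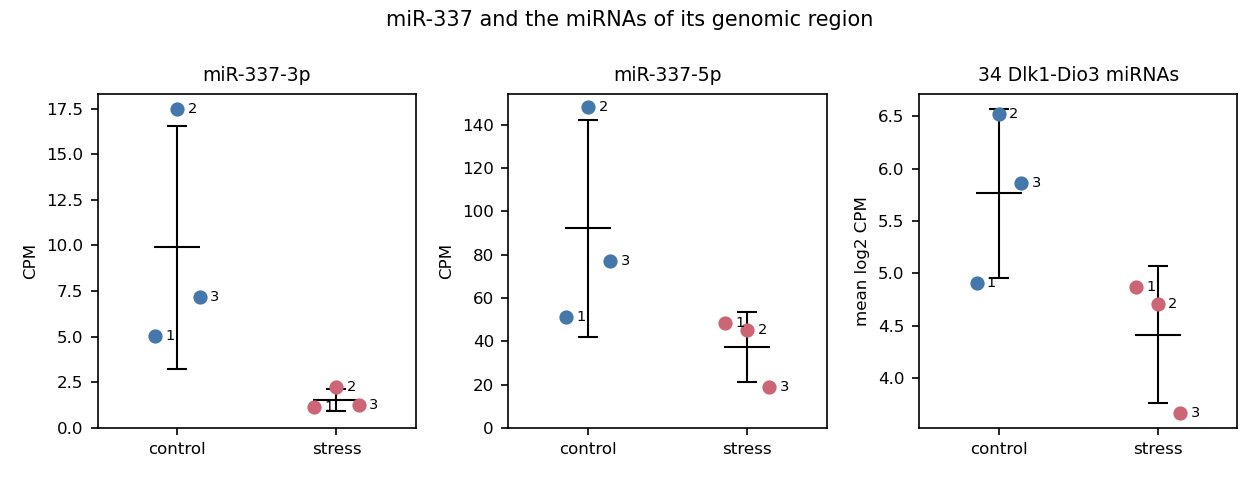
CPM of miR-337-3p and miR-337-5p and the mean log2 CPM of 34 Dlk1-Dio3 miRNAs in each control and stress library (points, numbered by replicate), with the mean (bar) and SD (whiskers) of 3 libraries per group. Stress libraries lie lower in each panel, and control replicate 1, at a list mean of 4.91, lies next to stress replicate 1 at 4.87.

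**Figure D4:**
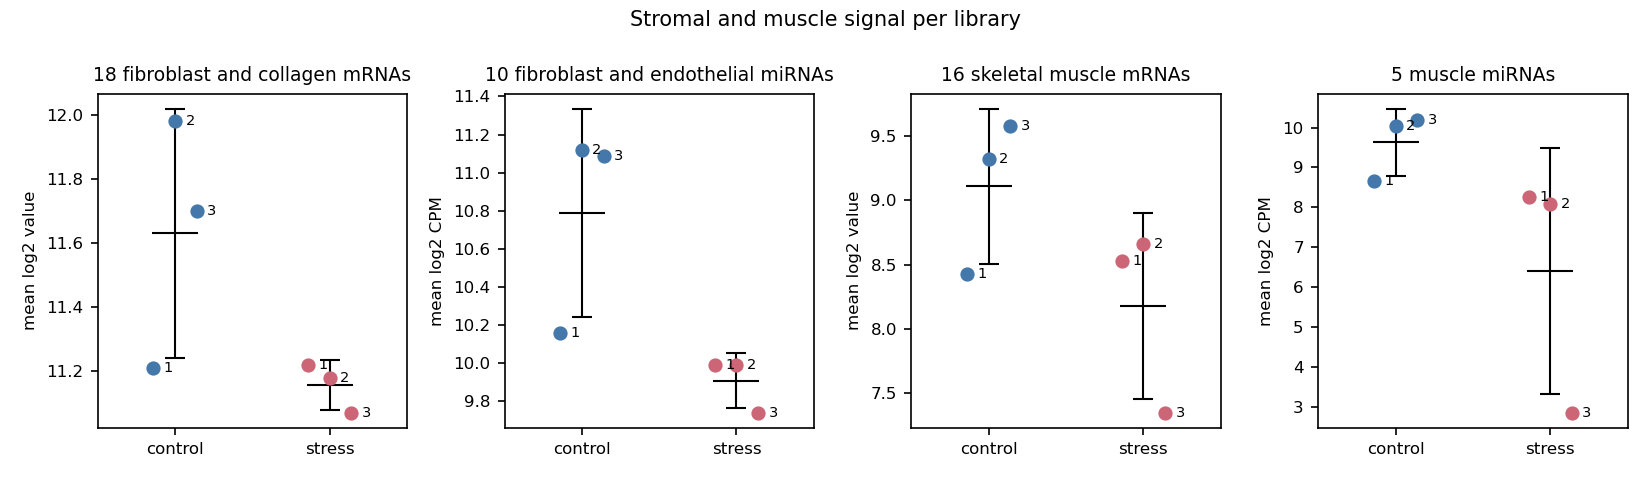
Mean level of fibroblast and collagen mRNAs, fibroblast and endothelial miRNAs, skeletal muscle mRNAs and muscle miRNAs in each library (points, numbered by replicate), with the mean (bar) and SD (whiskers) of 3 libraries per group; mRNA means are in deposited log2 values and miRNA means in log2 CPM. Control replicate 1 lies close to stress replicates 1 and 2 in each panel, and stress replicate 3 is lowest, at 7.35 for muscle mRNAs and 2.85 for muscle miRNAs.

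The miR-200 family, abundant in epithelial cells, was called higher: all 7 tested members of its list were higher (miR-205-5p, the other member fixed, was not tested), with a mean of 0.56 (adjusted p = 0.00266, adjusted p = 0.374 with an estimated correlation), and none passed either adjustment. The members with the smallest p were miR-200b-5p (0.72 higher, adjusted p = 0.181) and miR-141-3p (0.94 higher, adjusted p = 0.214). Without control replicate 3 the list mean was 0.32 (adjusted p = 0.0450). In the same libraries the means of the fibroblast and endothelial miRNAs (-0.96) and of the muscle miRNAs (-2.11) were lower. Erythroid miRNAs (5 of 7 higher, adjusted p = 0.571), leukocyte miRNAs (3 of 10 higher, adjusted p = 0.571), the let-7 family (all 9 higher, mean 0.10, adjusted p = 0.389) and the miR-17-92 and paralogous clusters (7 of 12 higher, adjusted p = 0.491) were not called. Without control replicate 2 the erythroid miRNAs were called higher, with a mean of 0.59 (adjusted p = 0.00437), against 0.09 with all libraries. The smallest p-values belonged to miR-16-5p (-0.39, adjusted p = 0.288) and miR-144-3p (0.42 higher, adjusted p = 0.661), miR-146a-5p (-0.47, adjusted p = 0.165) and miR-223-3p (0.70 higher, adjusted p = 0.178), let-7c-5p (0.28 higher, adjusted p = 0.242) and let-7f-5p (0.13 higher, adjusted p = 0.555), and miR-25-3p and miR-93-5p (0.29 higher, adjusted p = 0.247). Of these miR-25-3p passed adjusted over the list alone (0.52 higher, adjusted p = 0.138 over all miRNAs).

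Across all 462 miRNAs edgeR called 0 higher and 0 lower, while 40 were higher and 70 lower at an unadjusted p of 0.05. DESeq2 was fitted to the 1123 miRNAs with at least 1 read and left out low counts by its own filter before adjustment. It called 10 higher and 34 lower. On the 462 miRNAs limma-voom called 0 and 0. Without control replicate 1, edgeR called 18 higher and 64 lower. Among miRNAs with a mean of at least 10 CPM, the smallest p-values on the lower side belonged to miR-143-3p, miR-145a-3p (-1.37), miR-145a-5p, miR-381-3p and miR-34b-5p (-1.39), each with an adjusted p of 0.138. On the higher side they belonged to miR-5121 (1.89 higher), miR-25-3p, miR-27a-3p (0.65 higher) and miR-27b-3p (0.45 higher), with an adjusted p of 0.138, and to miR-3068-3p (1.31 higher, adjusted p = 0.144).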

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

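Median centring, quantile normalization, the stricter filter on the log2 values, the fit without a variance trend, the sums over precursor rows and the muscle covariate were chosen after seeing the data. The mRNA table holds log2 values, so DESeq2, limma-voom, size factors and total counts were not run on it. Stat3 stayed higher and short of the threshold in 15 alternatives (0.18 to 0.28, adjusted p 0.122 to 0.582).

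At an adjusted p of 0.1 in place of 0.05, 47 genes were higher and 48 lower. The stricter filter gave 7 lower genes and quantile normalization 5. With a muscle covariate 0 genes were higher and 0 lower, although the 5 differences stayed near their size (Hspa1b 1.14 against 1.18), and without single libraries 0 to 4 were higher and 0 to 2 lower. The cause was not tested. Gene lists called fell from 14 to 0 with an estimated correlation, and miRNA lists from 4 to 0. Without a library 11 to 16 gene lists and 4 to 5 miRNA lists were called.

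DESeq2, fitted to the 1123 miRNAs with at least 1 read and with its own filter before adjustment, called 10 higher and 34 lower. It gave miR-337-3p a log2 difference of -2.70, past the threshold. With edgeR and without the filter on low counts the counts were 18 and 51, and miR-337-3p, at -2.62, passed. Its p in that fit rested almost wholly on a spread pooled over miRNAs. Without single libraries 0 to 18 miRNAs were higher and 0 to 64 lower, and miR-337-3p ran from -3.00 to -1.96. Its call appeared without control replicate 1 (adjusted p = 0.0105) and in no other of these 6 fits. The cause was not tested. A minimum of 50 CPM removed miR-337-3p. In 16 alternatives it stayed lower.

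Of the lists whose mean changed sign in an alternative, 3 were called with all libraries or in that alternative. Without single libraries the mean of erythroid markers ran from -0.170 to 0.225, above 0 and called without control replicate 2 (adjusted p = 0.0143), and that of macrophage markers from -0.114 to 0.0830, called without stress replicate 3 (adjusted p = 0.0154). Neither was called with all libraries. With a muscle covariate macrophage markers were at 0.187 (adjusted p = 0.00457) and cytosolic ribosomal proteins at -0.0295 (adjusted p = 0.284).

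Replicate numbers did not pair the libraries: among the stress libraries replicate 2 alone correlated best with the control library of its number. Deviations of same-numbered libraries correlated at -0.08, 0.08 and -0.02 in the mRNA table and at -0.48, 0.32 and -0.13 in the miRNA table. With the replicate number as a block, 0 genes were higher and 0 lower, 14 gene lists and 4 miRNA lists were called, and 0 miRNAs passed in either direction. Counts of miR-337-3p were few, 2 to 48 per library. The depth of the mRNA libraries is unknown.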

Other observations

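Tests of tumour cell share and of a delay before freezing were chosen only after the result was seen, as were the correlations between libraries of the same number, the clock gene lists, the list of immediate early genes and the muscle covariate of the mRNA fit. Of 7 tested clock output genes, all were higher in stress, with a list mean 0.42 higher (95% interval 0.145 to 0.694). They include Nr1d1, a clock repressor (0.56 higher, limma adjusted p = 0.202), Ciart (0.64 higher, adjusted p = 0.129) and Per3 (0.37 higher, adjusted p = 0.120). Clock activators Arntl, Npas2 and Clock had a mean difference of -0.05 (95% interval -0.306 to 0.209). Per2 (0.49 higher, adjusted p = 0.0647) and Bhlhe41 (0.61 higher, adjusted p = 0.0769) stood higher too. These last genes are in neither clock list and were named after their values were seen. None of these genes passed the threshold.

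The Dlk1-Dio3 miRNAs, miR-337-3p among them, were lower in stress by a list mean of -1.35 log2 CPM (95% interval -3.01 to 0.313). Over the 6 libraries of the same group and number, this mean followed the fibroblast and collagen mRNAs (Pearson r = 0.946, exact permutation p = 0.00278; Spearman rho = 0.943, p = 0.0167; r = 0.991 without the 2 libraries farthest from the median) and the muscle mRNAs (r = 0.928, p = 0.0167; rho = 0.714, p = 0.136; r = 0.943). Among 4 such relations the Benjamini-Hochberg adjusted p for r was 0.00834 and 0.0167, and for rho 0.0334 and 0.136, which partly restates the group difference: with group means removed and permutation within groups, r was 0.885 (exact p = 0.0278, adjusted 0.0556) and 0.875 (exact p = 0.111, adjusted 0.111). With fibroblast and endothelial miRNAs as a covariate the difference became 0.0464 (95% interval -1.86 to 1.96), and with muscle miRNAs -0.527 (-2.34 to 1.28). Less stroma or less muscle in the sampled pieces may account for the pattern, but both intervals also hold the uncorrected difference, and an effect of restraint on these miRNAs or on the stroma itself stays open.

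For miR-337-3p itself, release of its targets was tested in the mRNA table. Of 13309 genes with an annotated 3' UTR, 3125 have a match to bases 2 to 8 of the miRNA, or to bases 2 to 7 followed by A. Stat3 has 3 such sites, in 8-base windows that start at bases 96, 464 and 1583 after its stop codon. In the window at 1583 the first base is not part of the match. Matched on UTR length and expression, the median difference of genes with a site exceeded that of genes without by 6.57e-05 (95% interval -0.00616 to 0.00596). The permutation p was 0.982 over 100000 draws across genes, which are not independent replicates. No general release of these mRNAs was seen. At rank 436 of 462 by mean CPM the miRNA is scarce, so little release could be seen even if its fall is real, and single targets stay untested.

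Proliferation genes were lower in stress by 0.27 (95% interval of the list mean -0.419 to -0.125). A smaller share of tumour cells would lower the epithelial mean as well. The gap between the epithelial and the proliferation mean widened by 0.302 (0.0268 to 0.578), nearly all of it from the proliferation genes. That interval excludes an unchanged gap, which a smaller share of tumour cells alone would give if it lowered both list means alike. For these lists the values therefore argue against a smaller share as the only cause. The epithelial interval given next reaches -0.166, so a small drop in the share stays open. The epithelial mean was 0.03 higher (-0.166 to 0.226), with a sign that turned without stress replicate 1 (-0.0226), without control replicate 3 (-0.00479) and with a muscle covariate (-0.00812), while the proliferation mean stayed between -0.310 and -0.234 without single libraries. Muscle carried over into the libraries points the other way. The muscle mean was lower in stress (-0.93), and more muscle in the controls would dilute proliferation genes there. With the muscle mean as a covariate the difference stayed at -0.206 (-0.381 to -0.0312). Slower cycling under restraint stays a hypothesis, as other differences between the tumours, such as size, are not given.

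Hspa1b was higher in stress past the threshold. Hspa1a (limma adjusted p = 0.0619), Per2 (0.0647) and Bhlhe41 (0.0769), all named after their values were seen, stood higher without passing it. The clock output list mean exceeded that of the clock activators, stress minus control, by 0.468 (95% interval 0.107 to 0.829), nearly all of it from the output genes. Another time of day, which would move both lists in opposite directions, cannot be told apart, because the interval of the activators (-0.306 to 0.209) covers 0. Glucocorticoid release, which could raise Per1, stays open as well. A longer delay before freezing cannot be told apart, because the immediate early genes differed by 0.0245 with an interval of -0.561 to 0.610.

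Among the 10 splits of the 6 libraries into 3 and 3, the real one called 5 genes and no other more than 1. For gene lists the real split called 14 and the highest other 17, so that 2 splits reached the real count. For miRNA lists it called 4, as did the highest other, and 3 splits reached that count. For single miRNAs it called 0, as did all 10. With 10 splits no share under 0.05 can be reached.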
